A study of Mus musculus with 16 samples.

How the data were processed

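The series holds 16 samples of 2 mouse lines: 6 RNA-Seq libraries, 3 of P6D4 and 3 of 70Z/3, and 10 ChIP-Seq samples, 5 per line (Miz1, 3 histone marks and an input). Processed values of the RNA-Seq and Miz1 samples were analysed, and the histone mark and input samples were not analysed here. Groups and replicate numbers were taken from the sample titles and the cell line labels.

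The deposited RNA-Seq values are whole-number counts per Ensembl gene, 1 file per library, not normalised. Per the submitters' processing notes the tools of the series were TopHat2 2.0.10, Bowtie2 2.10, SAMtools, bedtools and HTSeq, with mm10 and GRCm38 as builds. Per the labels' protocols the library kit keeps strand; the strand setting used in counting is not given in the sources used here, so overlapping and antisense genes can share counts. Each file ends with 5 HTSeq summary lines that name no gene and were left out. Reads outside genes made up 14.5 to 16.0% of uniquely aligned reads and ambiguous ones 0.382 to 0.424%. Alignments that were not unique numbered 1.10 to 1.14 per gene count in P6D4 and 1.41 to 1.44 in 70Z/3, so reads of near-identical genes are partly uncounted. Mitochondrial genes took 2.27 to 2.67% of counts. Of 38293 genes, 36345 had a symbol in the name table used, and genes without one held 0.323% of counts.

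The Miz1 peak lists were made by the authors with MACS 2.0.10.20120913, per the file headers, on 1 ChIP library per line, with a q-value threshold of 0.01, 1 tag kept per position, 50 bp tags and fragment lengths of 271 bp (P6D4) and 270 bp (70Z/3). The controls are named only by number in the headers. The deposited values per peak are a pileup of tags at the summit (signal scaled between ChIP and control, per the file headers), a fold (ratio of pileup over the local background) and -log10 p and -log10 q. These scores are the authors' and were used to describe, rank or filter peaks within a list. The exception is the threshold for marked peaks given below. It comes from the 70Z/3 list and was applied to both lists, although their depth differs. The depositors typed remarks beside 2 peaks of the P6D4 list and 11 of the 70Z/3 list.

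Counts were normalised with TMM and tested with edgeR 4.0.16 (filterByExpr, quasi-likelihood fit and test, Benjamini-Hochberg adjusted p under 0.05), with cell line as the only term. Differences over 2-fold were tested with glmTreat at a log2 fold change of 1. CPM use the TMM-scaled library sizes. The SE of a log2 fold change is its size divided by the square root of the test's F. It is not a fitted standard error, and it understates counting error for genes with few counts in the lower line. A gene at 0 in all libraries of a line was given a fold against a floor of 3 counts per library (0.0666 CPM in 70Z/3 and 0.0616 CPM in P6D4), and a gene with 1 to 3 counts a ratio with an exact 95% counting interval; both cover counting error only. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry as alternatives. The 20 lists were pre-B, thymocyte, progenitor, Notch, V(D)J recombination, p53, IL-7, Myc and partners, Miz1 cell cycle targets, autophagy and vesicle transport, MHC class II, NF-kB, interferon, proliferation, nucleolar, cytosolic ribosomal protein, myeloid, NK and innate lymphoid, erythroid and stromal genes. Of their members, 7 symbols had no match and 60 had counts too low to test. The numbered replicates carry no stated pairing, so no block entered the main test.

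Genes were named by a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher line, all 3 libraries of one line above all 3 of the other and an established symbol. It adds the 2 most raised and 2 most lowered called members of each list, and a fixed set (Zbtb17, Trp53, Rpl22, Rpl22l1, Cdkn1a, Mdm2, Rag1, Rag2, Prkdc, Il7r, Socs1, Bcl2, Myc, Notch1 and Cd3e, and a gene that is not reported here). For peaks it takes the 5 gene-end peaks with the highest fold per list, the 5 highest found in one list only, and those of the fixed set. Genes named outside this rule are marked as such. The gene lists, tests and most alternatives were also fixed then.

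Peaks were compared with bedtools 2.31.1 by an overlap of at least 1 bp, and with 100 shuffles within chromosomes. The plan was to place peaks at transcription start sites. The RefSeq table used (GRCm38.p6, the build of the peak lists) gives gene bounds without strand, so a summit within 1 kb of either end of 21887 protein-coding genes was used. Shares carry Clopper-Pearson 95% intervals (scipy 1.17.1). Set medians were compared with 10000 random sets matched on mean expression, and lists with two-sided Fisher's exact tests adjusted over 40 tests. Figures were drawn with matplotlib 3.10.9 and R was version 4.3.3.

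The count tests were tested on simulated data before use, in 10 draws with 13750 genes at the real means and library sizes, 200 of them changed. The edgeR test recovered 74.0% of genes changed by a log2 of 0.5 (65.7 to 80.6% over draws), 92.7% (79.1 to 98.5%) at 1 and 98.3% (95.5 to 100%) at 2, with 0 calls of the wrong sign. Of its calls, 8.24% were false on average (5.85 to 11.8%), above the nominal 5.00%, while 4.93% of unchanged genes had an unadjusted p under 0.05. The test against 2-fold made 0.1 false calls per draw. The simulation used means over both lines and few changed genes. In the data 11891 genes were called, some with far larger changes, so these rates may not hold there. The set test, run on 1 draw, called the planted set and 0 of 20 unchanged sets. Genes were drawn independently there, so it does not test the preset correlation on lists whose genes move together. The peak overlap step found 200 of 200 planted overlaps.

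Alternatives were DESeq2 size factors and upper quartile scaling in edgeR, no filter on low counts, a filter of CPM over 1 in 3 libraries, each replicate left out in turn, the replicate number as a block, an adjusted p under 0.01, the Wald test of DESeq2 1.42.0 (2774 genes without an adjusted p were left missing), fold and p past a threshold in place of glmTreat, other overlaps, windows of 500 bp and 5 kb, the top 50% of each peak list and lists of equal length. Peaks at least as significant as the last one the depositors' remarks in the 70Z/3 list accept (-log10 q of 29.03, rank 315), called marked peaks, were added after seeing the data, as was leaving out the genes of chromosome 15 from the test of genes with a peak.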

Results

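Gene expression and the chromosomal binding of Miz1 were measured in 2 mouse lymphoid cell lines. 70Z/3 is a lymphoblast line at the pre-B stage of B cell development. P6D4 comes from the SCID.adh thymic lymphoma and is labelled as DN3, an early thymocyte stage before the T cell receptor is complete. Miz1, encoded by Zbtb17, is a zinc finger transcription factor that can activate genes on its own and repress them together with Myc. RNA-Seq was done on 3 libraries per line, with 54.8, 52.1 and 48.3 M counts in genes for P6D4 and 47.6, 48.9 and 45.5 M for 70Z/3. Miz1 ChIP-Seq was done once per line, so nothing measured from the peaks has a replicate check. The labels call the RNA libraries replicates without saying that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No pair of RNA libraries was identical, and replicates of a line differed by more than sampling noise (chi-square per degree of freedom 2.56 to 14.7). Correlations of log2 CPM across genes were 0.997 to 0.998 within a line and 0.645 to 0.658 between lines.

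The RNA comparison asks how the early B and early T lineage lines differ in expression. Lineage and cell line coincide here, so an effect of lineage cannot be separated from other differences between the lines. The p-values of genes and lists therefore compare these lines and not the lineages at large. The lines differed in most of the genes that could be tested. Most of the listed pre-B genes were higher in 70Z/3 and most of the listed thymocyte genes higher in P6D4. Of 13750 genes tested, 5955 were higher and 5936 lower in P6D4 at an adjusted p under the threshold (edgeR quasi-likelihood test). Against a 2-fold difference, 2277 genes were higher and 2561 lower. The biological coefficient of variation between libraries of a line was 4.08%, so small differences also passed the test against no change.

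The 10 genes with the highest fitted rise in P6D4 had no count in any 70Z/3 library. Their folds are therefore lower bounds against a floor of 3 counts per library, and they are not shown to exceed those of genes with a few counts in the lower line, such as Snx18 and Lrp12. The 10 genes with the highest fitted fall are bounded in the same way. Stra6, a membrane receptor for retinol uptake, reached 70.4 ± 0.549 CPM (SD, n = 3) in P6D4, at least 1056-fold higher than in 70Z/3. Prkar2b, a regulatory subunit of protein kinase A, was at least 794-fold higher, the zinc finger gene Zfp362 at least 643-fold and the somatostatin receptor Sstr2 at least 410-fold. Fzd4, a Wnt receptor, and Ephb6, an ephrin receptor, were at least 352-fold and 349-fold higher. Zkscan7, Sh3bp4, Cnnm1 and Syt13 had bounds from 275-fold down to 253-fold. In the other direction, Abracl had no count in P6D4 and 86.8 ± 4.20 CPM (SD, n = 3) in 70Z/3, at least 1410-fold lower in P6D4. Pde4b, a cyclic AMP phosphodiesterase, was at least 1107-fold lower, the elongation factor Ell2 at least 869-fold, the homeobox gene Hoxb8 at least 868-fold and Cobll1 at least 853-fold. Siglecg, an inhibitory receptor of B cells, was at least 755-fold lower, and Ubqln2, Zfp831, Rnf144a and Tmem26 had bounds from 788-fold down to 658-fold. The edgeR adjusted p of these 20 genes was at most 6.09e-12.

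Genes of the pre-B lineage were nearly all lower in P6D4. Of 24 members tested, 0 were higher and 23 were lower, with a median log2 fold change of -9.60 (camera adjusted p = 6.18e-08; adjusted p = 0.0553 with an estimated correlation). Ebf1, a transcription factor that sets up the B lineage, was at 305 ± 19.3 CPM (SD, n = 3) in 70Z/3 and 0.0752 ± 0.0457 CPM in P6D4. Its log2 fold change was -11.91 ± 0.12 (SE, edgeR adjusted p = 8.7e-18). Here and below, such SE understate counting error where the lower line has few counts, 12 in all for Ebf1. The Src family kinase gene Blk had 2 counts in P6D4 in all, a ratio of 4153 in favour of 70Z/3 with a 95% counting interval of 1150 to 34290. The member that missed the threshold, named after its values were seen, was Spib at 1.85 CPM in P6D4 and 2.20 CPM in 70Z/3 (edgeR adjusted p = 0.164).

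Thymocyte genes ran the other way. Of 28 members tested, 25 were higher in P6D4 and 3 lower, with a median log2 fold change of 5.31, or 5.29 with the genes at 0 taken at their bounds (camera adjusted p = 4.51e-06; adjusted p = 0.369 with an estimated correlation). Thy1, a surface glycoprotein of T cells, was at 669 ± 14.1 CPM in P6D4 and 0.304 ± 0.135 CPM in 70Z/3 (SD, n = 3). Cd3e, a signalling chain of the T cell receptor complex, had a log2 fold change of 10.87 ± 0.07 (SE; edgeR adjusted p = 1.17e-18). Trbc2, a constant region of the receptor's beta chain, was at least 165-fold higher. The 3 members that were lower were Cd5, Lef1 and Zap70, at -4.40, -3.29 and -0.82 on the log2 scale. Zap70 was named after its values were seen. Lef1, a partner of beta-catenin, was at 591 CPM in 70Z/3 against 60.4 CPM in P6D4.

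**Figure D1:**
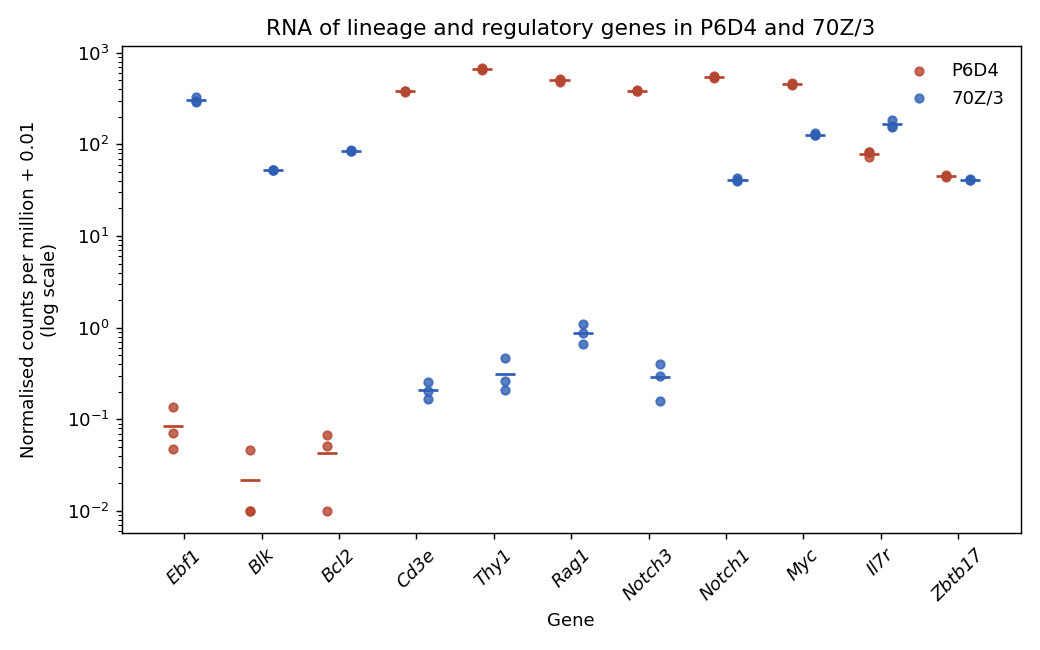
RNA of 11 lineage and regulatory genes. The vertical axis gives normalised read counts (CPM) plus 0.01 on a log scale, points are the 3 libraries of each line (P6D4 red, 70Z/3 blue) and bars are means. Ebf1, Blk and Bcl2 lie below 1 CPM in P6D4, Cd3e, Thy1, Rag1 and Notch3 lie at 0.199 to 0.873 CPM in 70Z/3, and Zbtb17 lies at 45.4 and 41.1 CPM.

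Most of the early progenitor genes that could be tested were lower in P6D4. Of 15 members, 7 had counts too low to test, and 7 of the 8 tested were lower, with a median log2 fold change of -11.08 (camera adjusted p = 0.0178; adjusted p = 0.369 with an estimated correlation). Bcl11a, a transcription factor of lymphoid progenitors and B cells, differed by -11.87 ± 0.13 (SE). Lmo2, a bridging protein of haematopoietic transcription complexes, had 1 count in P6D4 against 67.5 CPM in 70Z/3, a ratio of 10590 with an interval of 1901 to 418400. The cytokine receptor Flt3 was higher in P6D4, by 1.78 ± 0.18.

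The Notch list split evenly, with 9 of 18 members higher and 9 lower in P6D4 (median log2 fold change 0.07, camera adjusted p = 0.886). Notch1 was at 546 ± 8.74 CPM in P6D4 and 41.1 ± 1.55 CPM in 70Z/3 (SD, n = 3), a log2 fold change of 3.73 ± 0.04 (SE). Notch3 was higher by 10.43 ± 0.09. Ptcra, the invariant chain of the pre-T cell receptor, had 3 counts in 70Z/3 and a ratio of 1428 (interval 489 to 6925). Lfng, a glycosyltransferase that modifies Notch receptors, fell by 9.51 on the log2 scale in P6D4, and the Notch target Hes5 by 3.25.

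Among 18 genes of V(D)J recombination and end joining, 11 were higher in P6D4, 6 lower and 1 was not called (median 0.33, camera adjusted p = 0.407). Rag1, which encodes a subunit of the recombinase, was at 503 ± 22.6 CPM in P6D4 and 0.873 ± 0.214 CPM in 70Z/3 (SD, n = 3), and Rag2 was higher by 5.46 ± 0.13 (SE) on the log2 scale. Dntt, the polymerase that adds bases at the joints, was lower in P6D4, by -6.48 ± 0.15. Prkdc, the kinase of end joining that is mutated in SCID mice, was lower by -0.77 ± 0.04, and Hmgb1 by -1.13 ± 0.04. The uncalled member was Hmgb2, at 486 and 477 CPM, named after its values were seen.

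Cytokine and survival genes of the IL-7 list were divided: 6 of 16 members were higher, 9 lower and 1, Mcl1, was not called (median -0.94, camera adjusted p = 0.407). Mcl1, named after its values were seen, was at 186 CPM in both lines. Bcl2, an inhibitor of apoptosis, was at 85.6 ± 0.971 CPM in 70Z/3 and had 5 counts in all in P6D4. Its log2 fold change was -11.28 ± 0.13 (SE, edgeR adjusted p = 4.01e-17). Ccnd2, a D-type cyclin, was lower by -11.53 ± 0.11, with 4 counts in all in P6D4. Both SE understate the counting error of so few counts. Il7r, the receptor chain for IL-7, was at 79.1 ± 5.52 CPM in P6D4 and 167 ± 17.3 CPM in 70Z/3 (SD, n = 3), lower by the edgeR test against no change (adjusted p = 2.77e-09) and not called against a 2-fold difference (adjusted p = 0.126). Socs3, an inhibitor of cytokine signalling, had 1 count in 70Z/3 and 13.6 CPM in P6D4, a ratio of 1912 (interval 343 to 75510). The kinase Pim1 was higher by 1.37 ± 0.08. Socs1 had too few counts to be tested, with 0 in each P6D4 library and 11, 9 and 11 in 70Z/3.

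Zbtb17 itself was at 45.4 ± 0.887 CPM in P6D4 and 41.1 ± 0.506 CPM in 70Z/3 (SD, n = 3), a log2 fold change of 0.14 ± 0.04 (SE; edgeR adjusted p = 0.00426). In the list of Myc and its partners, 6 of 10 genes were higher and 4 lower (median 0.23, camera adjusted p = 0.597). Myc was higher in P6D4, at 457 ± 12.7 against 128 ± 3.41 CPM, and its antagonist Mxi1 was higher by 3.02 ± 0.07. Mxd1 and Mxd4, which compete with Myc for Max, were lower by -0.94 and -0.84. Max and Mnt, named after their values were seen, were lower by -0.36 and -0.15. Of 7 cell cycle and adhesion genes known as Miz1 targets, 2 were higher and 5 lower (median -0.59, camera adjusted p = 0.407). In neither Miz1 peak list did any of these 7 genes have a summit within 1 kb of a gene end. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, was higher by 1.39 ± 0.09 and the integrin gene Itgb1 by 0.27 ± 0.04. Cdkn2a had no count in P6D4 and 14.2 ± 0.762 CPM in 70Z/3, at least 230-fold lower. Bcl2 is given above, and the other lower members were Ccnd1, Cdkn1b and Itga6, at -0.67, -0.58 and -0.35, named after their values were seen.

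The p53 list had 11 members higher, 12 lower and 1 not called of 24 (median -0.14, camera adjusted p = 0.956). Trp53 itself was lower in P6D4, at -0.25 ± 0.05 (SE) on the log2 scale, while its negative regulator Mdm2 was higher by 0.80 ± 0.04. Fas, a death receptor, and Btg2, an antiproliferative gene, were higher by 2.33 ± 0.13 and 1.93 ± 0.12. Pmaip1, which encodes the proapoptotic protein Noxa, had 1 count in P6D4 and 32.1 CPM in 70Z/3, a ratio of 5029 (interval 903 to 198600). The uncalled Tnfrsf10b, named after its values were seen, stayed at 0.320 and 0.379 CPM.

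Genes of autophagy and vesicle transport were mostly lower in P6D4. Of 33 tested, 24 were lower, 7 higher and 2 not called, with a median log2 fold change of -0.38 (camera adjusted p = 0.0242; adjusted p = 0.369 with an estimated correlation). Gabarapl1, a protein of the autophagosome membrane, was at 122 ± 3.97 CPM in 70Z/3 and 0.0389 ± 0.0214 CPM in P6D4 (SD, n = 3). Wipi1 had 1 count in P6D4, a ratio of 1118 (interval 200.7 to 44160). The autophagy receptor Sqstm1 and the conjugation gene Atg12 were higher, by 1.16 ± 0.04 and 0.95 ± 0.06 (SE). Becn1 and Atg5, named after their values were seen, were not called. NF-kB target genes were also mostly lower. Of 15 tested, 12 were lower, 1 higher and 2 not called, with a median of -2.02 (camera adjusted p = 0.00615; adjusted p = 0.608 with an estimated correlation). The chemokine Ccl3 was lower by -6.12 ± 0.27 and Bcl2a1b at least 114-fold. Bcl2a1b belongs to a family of near-identical copies, so its counts are uncertain. The cytokine gene Tnf was higher, by 0.86 ± 0.08 (SE), and Relb and Nfkb2, named after their values were seen, were not called.

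Of 82 genes of cytosolic ribosomal proteins, 57 were higher in P6D4, 15 lower and 10 not called, with a median log2 fold change of 0.21 (camera adjusted p = 0.00615, and 0.925 with an estimated correlation). The camera direction was up under each scaling tried. Against a 2-fold difference, 3 were higher and 2 lower. Rpl8 was at 2940 ± 27.6 CPM in P6D4 and 1300.0 ± 16.0 CPM in 70Z/3 (SD, n = 3), and Rps26 was higher by 1.19 ± 0.03 (SE). Rps2 and Rpl29 were lower, by -1.57 ± 0.03 and -1.30 ± 0.09. Rps26, Rps2 and Rpl29 have near-identical pseudogenes with which reads can be shared, so their values are uncertain. Rpl22 was at 466 ± 6.66 and 438 ± 9.43 CPM, a log2 fold change of 0.09 ± 0.03 (edgeR adjusted p = 0.019), a call that 6 of the alternative settings lost, among them those without P6D4 replicate 2, 70Z/3 replicate 2 and 70Z/3 replicate 3 (edgeR adjusted p = 0.0714, 0.102 and 0.112; range over all 0.000765 to 0.112). Its paralog Rpl22l1 was higher by 0.81 ± 0.04. Nucleolar and ribosome biogenesis genes had 9 of 23 members higher, 9 lower and 5 not called, with a median of 0.10 and a mean of -0.01 (camera adjusted p = 0.927). Bop1, which like Rpl8 lies on chromosome 15 (median 0.94 over its tested genes), and Nop56 were higher by 0.83 and 0.69. Utp20 and Polr1a were lower by -0.69 and -0.61. The uncalled genes, named after their values were seen, were Fbl, Dkc1, Odc1, Nop16 and Rrp9. Of 24 proliferation genes, 12 were higher, 9 lower and 3 not called (median 0.10, camera adjusted p = 0.65). The mitotic checkpoint kinase Bub1b and the kinase Cdk1 were higher by 1.66 ± 0.04 and 1.16 ± 0.03, and the helicase subunit Mcm3 and the transcription factor Foxm1 lower by -0.86 and -0.78. Mcm7, Pcna and Ccnb2, named after their values were seen, were not called.

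Interferon-induced genes split into 9 higher and 9 lower of 18 (median 0.27, camera adjusted p = 0.829). The antiviral GTPase Mx1 was at 62.6 ± 1.06 CPM in P6D4 and 0.113 ± 0.0412 CPM in 70Z/3 (SD, n = 3), and the nucleic acid sensor Zbp1 was higher by 4.03 ± 0.14 (SE). The RNA sensor Ifih1 and the antiviral gene Rsad2 were lower, by -8.69 ± 0.17 and -3.74 ± 0.24. Of 8 MHC class II genes, 4 were higher, 3 lower and 1 not called. Their median log2 fold change was 0.51 and their mean -1.11 (camera adjusted p = 0.886, direction up). H2-Ob, a subunit that modulates peptide loading, was at 81.2 ± 9.46 CPM in 70Z/3 and 0.478 ± 0.0793 CPM in P6D4, and H2-DMb1 had 3 counts in P6D4, a ratio of 23.4 (interval 8.01 to 114). H2-DMa and H2-Aa were higher by 1.32 ± 0.08 and 1.17 ± 0.13. H2-Ab1 and H2-Eb1 were each higher by 0.90, Cd74 was lower by -1.51 and H2-Oa was not called, all named after their values were seen.

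None of the 4 lists of markers of other cell types passed the camera test. Many of their members, fixed at 14 for NK and innate lymphoid, 19 for myeloid, 12 for erythroid and 12 for stromal markers, had too few counts to test or no matching symbol. Of 9 NK and innate lymphoid markers, 7 were higher in P6D4 and 2 lower, with a median log2 fold change of 8.95, or 7.09 with the genes at 0 at their bounds (camera adjusted p = 0.0701; adjusted p = 0.369 with an estimated correlation). The list passed without P6D4 replicate 1 (adjusted p = 0.0342) and without 70Z/3 replicate 1, 2 or 3 (0.0456, 0.0425 and 0.034), over a range of 0.0268 to 0.102. Rora was at 141 ± 16.8 CPM in P6D4 and 0.0567 ± 0.0525 CPM in 70Z/3 (SD, n = 3), and Zbtb16 was at least 136-fold higher. The lectin receptor Klrd1 was at least 341-fold lower and Klrb1c lower by -3.87 ± 0.26 (SE). Of 7 myeloid markers, 3 were higher and 4 lower (median -0.71, camera adjusted p = 0.886). Cebpb had 2 counts in 70Z/3 and 17.4 CPM in P6D4, a ratio of 1221 (interval 338 to 10080), and the integrin Itgam was higher by 2.04 ± 0.10. Cd68, named after its values were seen, was higher by 0.79. The growth factor receptor Csf1r had 2 counts in P6D4 and 2.84 CPM in 70Z/3, a ratio of 223 (interval 61.7 to 1842). Fcgr3 was lower by -3.84, and Lyz2 and Prtn3, named after their values were seen, by -2.64 and -0.70. Of 4 erythroid markers, 1 was higher and 3 lower, with a median of -0.75 and a mean of 0.56 (camera adjusted p = 0.757). The erythropoietin receptor Epor was at least 70.8-fold higher, Hbb-bt at least 5.70-fold lower, and the transferrin receptor Tfrc lower by -0.78. Klf1, named after its values were seen, was lower by -0.72. Stromal markers split into 3 higher and 3 lower of 6, with a median of -1.79, or -0.89 with bounds (camera adjusted p = 0.886). Vim, an intermediate filament gene, was at 309 ± 15.7 CPM in 70Z/3 and 0.104 ± 0.101 CPM in P6D4, and Lum was at least 22.5-fold lower. Thy1 is also a thymocyte gene and is given above, and Acta2 was higher by 3.95 ± 0.49. Pdgfrb and Sparc, named after their values were seen, were higher by 2.70 and lower by -6.28.

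Adjusted over the list alone, the counts of higher and lower members were identical to those adjusted over all genes tested for each of the 20 lists. In all, 6 lists passed limma's camera test with the preset correlation. With an estimated correlation 0 passed, and 1 had an unadjusted p under 0.05. By limma's fry test 18 passed, which asks whether a list's own genes move on balance one way and does not compare them with other genes.

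Miz1 binding was compared to find which sites the lines share. The deposited list labelled P6D4 held 21629 peaks and the list labelled 70Z/3 held 10462, from 60.8 and 30.9 M tags, of which 2.07 M (3.40%) and 4.48 M (14.5%) were kept after removal of duplicates, per the file headers. The peak lists are called by their labels throughout, because some of the strongest peaks found in one list only lay at genes with RNA in the other line, which leaves in doubt which line each list came from. Of the P6D4 list, 22.5% of peaks overlapped a peak of the other list by at least 1 bp, against 0.389% on average and 0.476% at most in 100 shuffles within chromosomes. Of the 70Z/3 list, 44.6% overlapped, against 0.756% on average and 1.06% at most. The shuffles place peaks evenly along each chromosome and take no account of regions prone to peaks in any library. An overlap above them does not by itself show shared Miz1 sites. Among the first 50 peaks of each list, 98.0% of the P6D4 list and 96.0% of the 70Z/3 list overlapped, and beyond rank 10000 it was 14.3% and 19.05%. The share did not fall evenly between these ends in the 70Z/3 list, with 37.0% past rank 100 and up to rank 200, and 79.2% past rank 500 and up to rank 1000. With 1 library per list, no p-value can be given for a difference in binding.

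**Figure D2:**
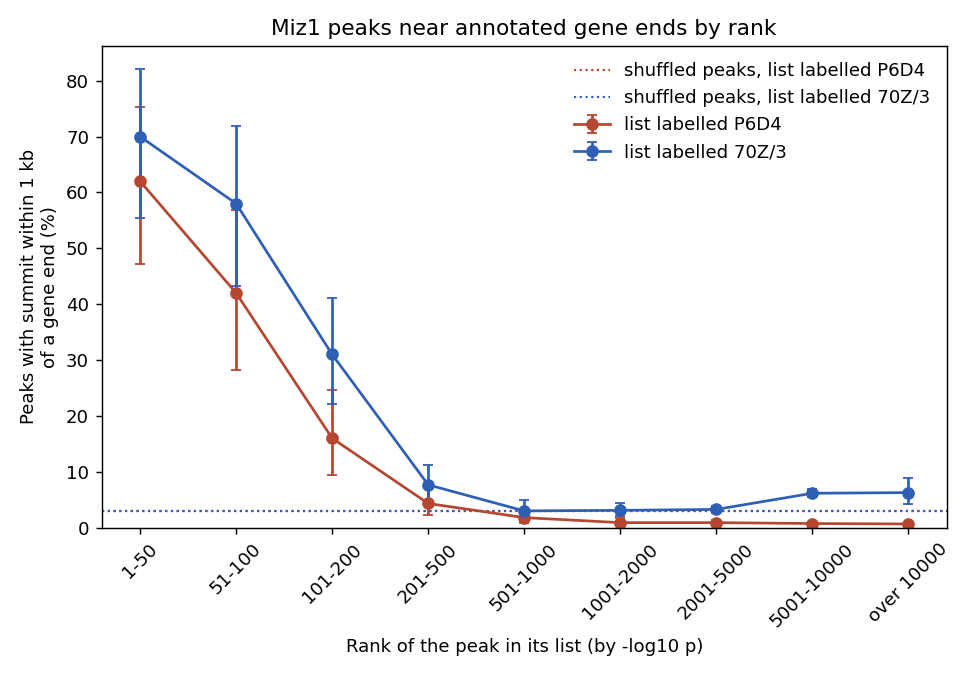
Share of Miz1 peaks with a summit within 1 kb of an annotated gene end (vertical axis, percent) by the rank of the peak in its list (horizontal axis). Points are shares with 95% exact binomial intervals, red for the list labelled P6D4 and blue for the list labelled 70Z/3, and dotted lines are the means of shuffled peaks. The share is 62.0% and 70.0% in the first 50 peaks and 0.662% and 6.28% beyond rank 10000; in the 70Z/3 list it is lowest, at 3.00%, past rank 500 and up to rank 1000.

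Most of the strongest Miz1 peaks lay at gene ends and most weak ones did not, although in the 70Z/3 list the share was higher past rank 5000 (6.16% up to rank 10000) than past rank 500 (3.00% up to rank 1000). Gene ends stand here for start sites, since the annotation used gives no strand, and either end of a protein-coding gene counts. Of the 50 most significant peaks, 62.0% of the P6D4 list (Clopper-Pearson 95% interval 47.2 to 75.4%) and 70.0% of the 70Z/3 list (55.4 to 82.1%) had their summit within 1 kb of a gene end. Over whole lists the share was 1.11% (0.974 to 1.26%) for P6D4, below the 2.96% of shuffled peaks, and 5.73% (5.29 to 6.19%) for 70Z/3, above the 3.00% of shuffled peaks. With a window of 5 kb the 70Z/3 share, 12.8%, lay within the range of shuffled peaks (11.9 to 13.4%). These intervals cover counting error only.

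The gene-end peaks with the highest fold over background by the authors' peak caller are given with positions on mm10/GRCm38. In the P6D4 list the first was chromosome 5, 139344891 to 139345586, with its summit 53 bp beyond the upper end of Cox19, a copper chaperone of mitochondria, at 133-fold. It was followed by C2cd5 (chromosome 6, 143099908 to 143100509, 79.4-fold), Exoc2, a subunit of the exocyst (chromosome 13, 30973854 to 30974373, 75.7-fold), the shared interval of Palb2 and Dctn5 (chromosome 7, 122132709 to 122133319, 69.6-fold) and the kinase gene Taok3 (chromosome 5, 117119706 to 117120383, 65.9-fold). In the 70Z/3 list the first was Hdgf (chromosome 3, 87905876 to 87906533) at 240-fold, with its summit 120 bp inside the gene. Lrp12 (chromosome 15, 39943784 to 39944605) followed at 239-fold, Vamp4, a SNARE protein of vesicle fusion (chromosome 1, 162570166 to 162571101), at 234-fold, Taok3 at 209-fold and the shared interval of Vps28, an endosomal sorting protein, and Tonsl (chromosome 15, 76625641 to 76626520) at 209-fold. All of these but Lrp12 overlapped a peak of the other list. No gene in the set that was always to be named had a summit within 1 kb. Rpl22 had a peak in both lists with its summit 1358 and 1355 bp inside its lower end, at 36.7-fold and 97.6-fold. Myc had one in the 70Z/3 list 2438 bp inside the gene at 12.7-fold, and Cdkn1a one in the P6D4 list 3415 bp beyond its upper end at 6.90-fold.

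Gene-end peaks found in one list only were led in the P6D4 list by Cand2 (chromosome 6, 115774139 to 115774513, 24.5-fold), Stau2 (chromosome 1, 16519398 to 16519716, 21.6-fold), Rasal2 (chromosome 1, 157412472 to 157412895, 16.5-fold), Slitrk3 (chromosome 3, 73057607 to 73058005, 16.1-fold) and the interval of Wdr12 and Carf (chromosome 1, 60097474 to 60097900, 16.1-fold). In the 70Z/3 list they were led by Lrp12, Snx18 (chromosome 13, 113618235 to 113618942, 200.1-fold), Zhx1 (chromosome 15, 58076043 to 58077081, 61.9-fold), the interval of Tmem25 and Ttc36 (chromosome 9, 44799010 to 44799709, 54.6-fold) and Ube3c (chromosome 5, 29568864 to 29569424, 38.2-fold). RNA of several of these genes was higher in the line whose list lacked the peak. Lrp12, a lipoprotein receptor family member, was at 65.1 ± 0.915 CPM in P6D4 and 0.0441 ± 0.0589 CPM in 70Z/3 (SD, n = 3). Snx18, a sorting nexin, was at 39.5 ± 2.23 CPM in P6D4 with 1 count in 70Z/3, a ratio of 5545 (interval 995 to 219000). Stau2 was at 87.0 ± 1.33 CPM in 70Z/3 and 0.0573 ± 0.0326 CPM in P6D4, and Rasal2 had 1 count in P6D4, a ratio of 3388 (interval 608 to 133800). Cand2 was lower in P6D4 by -5.20 ± 0.08 (SE). Ube3c was at 107 and 89.4 CPM.

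The last comparison asked whether genes with a gene-end peak differed in RNA between lines. Genes with a peak in both lists had a median log2 fold change of 0.07 over 105 tested (camera adjusted p = 0.457). Genes with a peak in the P6D4 list only had a median of 0.06 over 39 tested, with a mean of -0.81 and a camera direction of down (adjusted p = 0.969). With a window of 5 kb that median turned to -0.16 over 246 genes, outside the matched range of -0.14 to 0.15 (camera adjusted p = 0.143). Of the 361 genes tested with a peak in the list labelled 70Z/3 only, 203 were higher in P6D4, 118 lower and 40 not called. Their median was 0.25, beyond the 95% range of -0.09 to 0.11 for 10000 random sets matched on mean expression, and limma's camera did not pass the threshold (adjusted p = 0.0531; adjusted p = 0.288 with an estimated correlation). Chromosome 15, whose genes were higher in P6D4 as a whole, held 59 of the 361. Without it the median was 0.12 over 302 genes, against a matched range of -0.13 to 0.09 (camera adjusted p = 0.425), an alternative chosen after seeing the data. So 0 of the 3 sets passed, 1 had an unadjusted camera p under 0.05, and the 70Z/3 set passed in 6 of 17 alternatives, among them the one without 70Z/3 replicate 3 (adjusted p = 0.049; range over all 0.0036 to 0.425). RNA was high enough to test for 90.5% of genes with a peak in both lists, 76.97% with one in the 70Z/3 list only, 50.7% with one in the P6D4 list only and 56.9% of genes without a peak.

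Fisher's exact test found 0 of 40 combinations of gene list and peak list enriched for gene-end peaks (lowest adjusted p = 1.0), with 1 at an unadjusted p under the threshold of 0.05 (two-sided p = 0.0388). Autophagy and vesicle transport genes had a peak in 2 of 33 cases in the P6D4 list and 4 of 33 in the 70Z/3 list. Vamp4 and Ambra1, a regulator of autophagy, had one in both lists. So had Vps28, a member of the list left out of these counts because its symbol had no match among the counted genes, at 52.2-fold and 209-fold. The mitotic kinase gene Aurka had a peak in both lists, at 45.4-fold and 100.7-fold, as had Rpl9 at 30.8-fold and 54.9-fold; Ambra1, Aurka and Rpl9 were named after their values were seen.

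**Figure D3:**
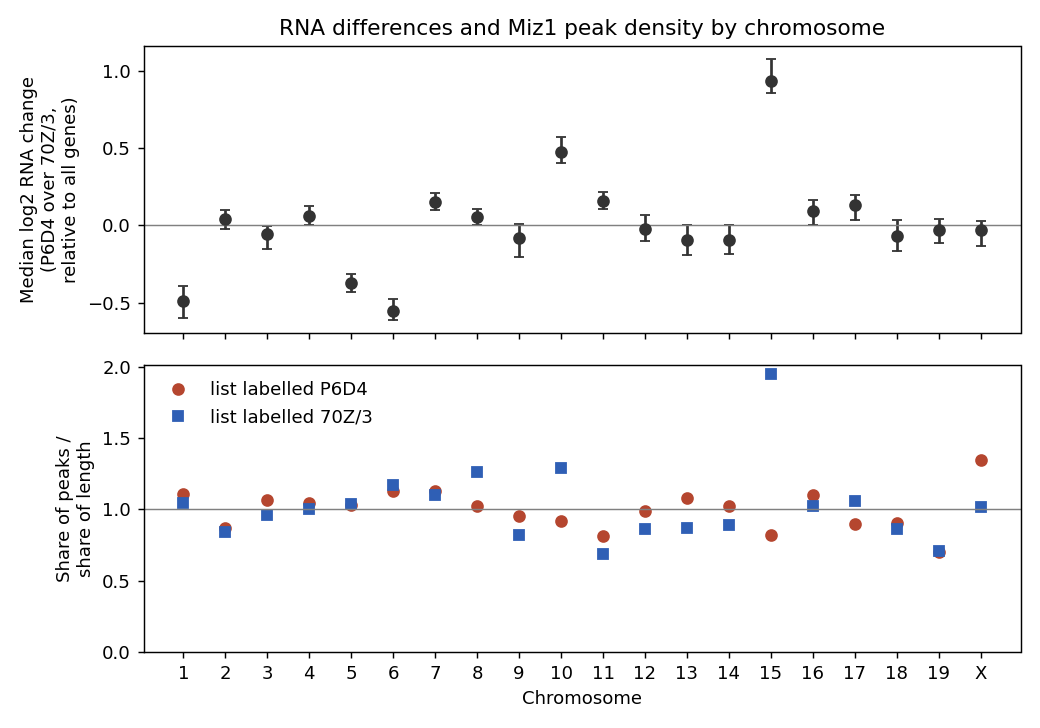
RNA differences and Miz1 peak density by chromosome. The upper panel gives the median log2 fold change of tested genes (P6D4 over 70Z/3) relative to all genes, with 95% bootstrap intervals, and the lower panel gives each list's share of peaks divided by the chromosome's share of length, red circles for the list labelled P6D4 and blue squares for the list labelled 70Z/3. Chromosome 15 stands at 0.94 in the upper panel and at 0.82 and 1.95 in the lower panel.

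Chromosome 15 carries Lrp12, Zhx1 and Vps28 and was singled out after its values were seen. It had a median log2 fold change of 0.94 relative to all genes (bootstrap 95% interval 0.85 to 1.08). In P6D4, 365 of its genes were higher and 72 lower (camera adjusted p = 1.96e-11, and 0.012 with an estimated correlation). It also carries Myc, Rpl8 and Bop1, higher by 1.84, 1.18 and 0.83, and Il7r, lower by -1.08. How far these rises go with the chromosome as a whole was not tested. The list labelled 70Z/3 held 1.95 times as many peaks there as the chromosome's length would give, and the list labelled P6D4 0.82 times. Within 5 kb of a gene end these values were 3.70 (interval 3.22 to 4.22) and 0.39 (0.23 to 0.61).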

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

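The threshold from the depositors' remarks (marked peaks) and leaving out chromosome 15 were chosen after seeing the data and all other alternatives before. Counts of called genes stayed within 1.5 times in every alternative, with 5329 to 6635 genes higher and 5308 to 6718 lower in P6D4 and over 2-fold 1808 to 2734 and 2122 to 3085. Of 102 named genes refitted in 13 settings, 102 kept their direction, and 1, Rpl22, lost its call, in 6 settings (adjusted p 0.000765 to 0.112). Zbtb17 stayed called (adjusted p 0.000326 to 0.0272). Same-numbered libraries of the lines did not deviate together (correlations -0.055, -0.046 and 0.008). No strong pairing by number was seen, and a weak one cannot be excluded this way. With the replicate number as a block, 5867 genes were higher and 5847 lower. Lists past the threshold were 6, but 0 with an estimated correlation and 18 with fry, whose construction differs. Lists that changed direction were far from the threshold with camera: the myeloid list at adjusted p 0.943 without a filter and 0.992 with CPM over 1, the erythroid list at 0.961 and 0.896, the p53 list at 0.993 with CPM over 1 and 0.917 to 0.994 with a replicate left out, and the nucleolar list at 0.854 to 0.994 with a replicate left out. With fry, MHC class II (0.00372) and erythroid markers (0.000813) took the other direction. The NK and innate lymphoid list passed without a filter (0.0268) and without P6D4 replicate 1 or any 1 of the 70Z/3 replicates (0.034 to 0.0456), over a range of 0.0268 to 0.102. The cause was not tested.

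For genes with a peak in the P6D4 list only, the camera direction turned to up, far from the threshold, without a filter (median 0.091), with the block (0.058), with 500 bp (0.061), with the top 50% of each list (0.157) and without P6D4 replicate 1 (0.053 to 0.121 over replicates left out); with marked peaks it stayed down, at -7.85 over 4 genes. The median itself turned to -0.022 with CPM over 1 and to -0.158 at 5 kb, where 94 genes were higher and 130 lower (adjusted p = 0.718 and 0.143). For the 70Z/3 list only, the set passed without a filter (0.277), with CPM over 1 (0.224), at 500 bp and 5 kb (0.28 each), with the top 50% (0.323) and without 70Z/3 replicate 3 (adjusted p = 0.049; medians 0.23 to 0.257 over replicates left out); adjusted p ranged from 0.0036 to 0.425, the highest without chromosome 15, where the median was 0.12. At 500 bp, 5 kb and the top 50% the call was lost with an estimated correlation (adjusted p = 0.343, 0.133 and 0.183) and without chromosome 15 (adjusted p = 0.377, 0.178 and 0.109), where the medians fell to 0.11, 0.144 and 0.213 over fewer genes, still at percentiles 98.15, 100 and 99.59 of matched random sets. Shared peaks of the P6D4 list were 11.8% at 50% reciprocal overlap, 14.0% with summits within 200 bp, 21.9% for the top 50%, 31.4% at equal length and 71.0% of marked peaks against all peaks of the other list, and of the 70Z/3 list 24.5%, 29.0%, 31.8% at equal length and 55.9% of marked peaks. Marked peaks against marked peaks only overlapped in 50.5% and 28.9%. Peaks at gene ends were 0.698% at 500 bp, 5.34% at 5 kb, 1.55% in the top 50% and 36.0% of marked peaks in the P6D4 list, and 4.16%, 12.8% and 33.3% at 500 bp, 5 kb and among marked peaks in the 70Z/3 list. These shares move because the alternatives redefine what counts. At 5 kb the 12.8% of the 70Z/3 list lies within the 11.9 to 13.4% of shuffled peaks. Depth differs between the lists, with 2.07 and 4.48 M tags kept, and its effect on weak sites was not tested.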

Other observations

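The tests of the P6D4 library's depth and of binding at chromosome 15 gene ends were chosen after the result was seen, as were the threshold for marked peaks, the comparison by chromosome and the values without chromosome 15; the other tests were written before. RNA differed by chromosome beyond chromosome 15. Genes of chromosome 10 were higher in P6D4, by a median log2 of 0.47 relative to all genes (bootstrap 95% interval 0.40 to 0.57). The camera adjusted p was 0.012 with an estimated correlation. Among its named genes, Mdm2, Rps26 and Cdk1 were higher, and Utp20, Abracl, Lum and Tmem26 lower. Genes of chromosomes 6, 1 and 5 were lower, by -0.55, -0.49 and -0.37 (adjusted p = 0.0161, 0.0132 and 0.0132 with an estimated correlation). Xist, the RNA that coats an inactive X chromosome, named after its values were seen, was at 4291 ± 250.0 CPM (SD, n = 3) in 70Z/3 and 1.75 ± 0.296 CPM in P6D4. Genes of the X chromosome stood at -0.03 relative to all genes. Its peaks were 1.34 times as many as its length would give in the list labelled P6D4 and 1.02 times in the list labelled 70Z/3. The number of X copies was not tested. Miz1 peaks crowded into several of the same places in both lists, with 82 peaks of the P6D4 list and 65 of the 70Z/3 list on chromosome 6 from 114400001 to 114600000, and 57 and 61 on chromosome 8 from 123400001 to 123600000 (mm10/GRCm38). An exception was chromosome 7 from 15200001 to 15400000, with 35 peaks of the 70Z/3 list and 0 of the P6D4 list.

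Some strong gene-end peaks found in one list only lay at genes with RNA mainly in the other line. Among marked peaks, 22 tested genes had one in the list labelled 70Z/3 only, of which 14 were higher and 6 lower in P6D4 (9 and 1 over 2-fold; camera adjusted p = 0.161, and 0.285 with an estimated correlation), and 4 had one in the list labelled P6D4 only, of which 1 was higher and 3 lower. Against the pattern, and named after their values were seen, Gm21814 with a peak in the 70Z/3 list was at 0.929 CPM in 70Z/3 and 0.0307 CPM in P6D4, and C8g with a peak in the P6D4 list was at 4.60 CPM in P6D4 and 0.540 CPM in 70Z/3. That a peak goes with lower RNA in its own line stays open, since the median of the 22 genes was at percentile 98.35 of matched random sets but at 70.63 without the 3 genes of chromosome 15; Snx18 had been seen before that test was written. Lower depth of the library labelled P6D4 also stays open. The 19 marked gene-end peaks of the 70Z/3 list without a counterpart had a median rank of 172 against 68 for the 86 with one (two-sided permutation p = 2e-05, the smallest the resamples can give). Depth would give this, but weaker peaks can lack a counterpart more often in any pair of lists, so the ranks cannot decide. The peaks of Lrp12 and Snx18 lack one even at ranks 4 and 10.

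Genes with a marked peak within 1 kb were left out of the test of the label doubt. It used genes with RNA in one line and a peak in one list. Of these, 67.7% (21 of 31, Clopper-Pearson 95% interval 48.6 to 83.3%) had the peak in the list of the line without RNA, where no association would give 63.2% (two-sided Fisher's exact p = 0.577). With a window of 5 kb it was 67.9% (76 of 112, against 49.2%; Fisher's exact p = 0.000101), or 66.3% without chromosome 15 (Fisher's exact p = 0.00105), and with the top 50% of each list 83.3% (10 of 12, interval 51.6 to 97.9%, against 72.2%; Fisher's exact p = 0.318). With a window of 500 bp it was 65.0% (13 of 20), below the 70.0% of no association (Fisher's exact p = 1.0). At 5 kb, genes with a marked peak beyond 1 kb could stay in, and genes that share a peak were each counted. The Fisher's exact p at 5 kb thus treats linked genes as separate and may draw on peaks that raised the doubt. Within 1 kb, a peak found only in the list labelled 70Z/3 lay at 3.65% of genes with RNA only in P6D4. It lay at 1.02% of those with RNA only in 70Z/3, or at 2.86% and 1.04% without chromosome 15. For the list labelled P6D4 these shares were 0.38% and 0.25%, on 2 genes each. The Fisher's exact test at 1 kb thus had little chance to find an association, and the shares were not tested by themselves. An exchange of the 2 list labels stays open, as does repression by Miz1 with correct labels. In 10 Mb windows outside chromosome 15, the peak and RNA differences had a rho of -0.166 over all peaks (16 of 1000 circular shifts as low), -0.048 over peaks beyond 5 kb of gene ends (249 of 1000) and -0.173 over gene-end peaks (5 of 1000), and these 2 explanations cannot be told apart: repression would leave the distal value near 0, as found, and either would give the gene-end value.

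Chromosome 15 is another place where the lists and the RNA part. Extra copies of chromosome 15 in 70Z/3 are argued against by its RNA, which stands at 0.935 in favour of P6D4, and binding at its gene ends alone by the distal peaks of the list labelled 70Z/3, which are 1.69 times (interval 1.56 to 1.83) as many as its length would give. The excess within 5 kb of gene ends was larger, 3.70 times (3.22 to 4.22), which a copy number that raised all peaks alike would not give. All 11 windows of the chromosome had a higher ratio of 70Z/3 to P6D4 peaks (0.55 to 2.54) than the genome (0.48), while RNA was higher in P6D4 in 10 of them, the exception being the window from 20 Mb with a median log2 fold change of -7.75 over 8 genes. An exchange of the labels, with extra copies in P6D4, may account for part of both. The peaks were called against controls named only by number, however. Whether extra copies would raise peak numbers over those controls was not tested. Chromosome 10 parted the same way by less. Its RNA stood at 0.472 in favour of P6D4, and its peaks at 1.29 times its length in the list labelled 70Z/3 and 0.92 times in the other. Chromosomes 1, 5 and 6, with RNA lower in P6D4, had log2 ratios of peak share (P6D4 list over 70Z/3 list) of 0.093, -0.008 and -0.053. Over the 18 autosomes other than 15, which are not independent replicates, rho was -0.24 (permutation p = 0.337), and -0.244 without the 2 farthest in RNA. Pearson's r was -0.352, and -0.166 without these 2. The exchange therefore cannot be told apart from other causes. No test run excludes the exchange. Its bounds set in advance were not reached by the tests as planned, though the 83.3% for the top 50% of each list, against 72.2% with no association, lies past the one for gene ends, with an interval that spans it. The RNA libraries carry the lineage genes of their labels.

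The 6 RNA libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes both lines in each group. The line difference then adds to the spread within groups, so few gene calls were bound to result. Part of it also remains between groups, so the other splits do not give a chance level. The real split gave 11891 called genes against 0 at most in the others, 4838 against 0 over 2-fold, 6 lists against 5, and 0 peak gene sets against 1. As many or more were found in 1, 1, 1 and 10 of the 10 splits.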
